A study of Mus musculus with 28 samples.

How the data were processed

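RNA was measured in 28 gastrocnemius libraries of male BALB/c mice from 5 groups: control (4), lactate (6), HIIT (6), MCT inhibitor (6) and HIIT plus MCT inhibitor (6). Per the labels' protocols, total RNA was extracted with a Zymo Quick-RNA Miniprep Plus kit, checked on a TapeStation, and made into Lexogen QuantSeq 3' mRNA libraries primed on the poly(A) tail, which hold molecular identifiers and were read as single ends on a NovaSeq X Plus. Such libraries count the 3' end of a transcript, so a gene's count does not scale with its length, and RNA without a poly(A) tail is poorly measured. Per the submitters' processing notes, the tools were FastQC, MultiQC, fastp, UMI-tools, cutadapt, STAR and SAMtools with the mouse build GRCm39, with no versions given. The counting program, the annotation release and whether counting used strand are not given in the sources used here.

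The deposited table holds whole-number counts per gene and library, made by the authors from deduplicated alignments, as its column names show, and not normalised. It has 41117 lines below its header and 41073 intact gene records, of which 22899 hold a count. The records of 6 long genes (Dst, Neb, Ttn, Syne1, Mycbp2 and Huwe1) were broken over several lines and left out, and 0 columns of values stayed unused. Each column name is given in the description of 1 sample. Coordinates are those of the table, on GRCm39. The reference in use here is GRCm38, so it served only for gene names and for the GC content of the last 300 bases of transcripts. No 2 libraries held identical values, and chi-square per degree of freedom between libraries of a group was 1.49 to 25.3 over 7968 genes, so each counted as 1 sample.

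Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 9110, scaled by TMM, and fitted by robust quasi-likelihood with group and sequencing batch over all 28 libraries. The common dispersion was 0.0218 (a biological coefficient of variation of 14.8%). All tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05, without a minimum fold change. Adjusted p-values of genes are edgeR's unless another tool is named. Batch 2 holds only HIIT replicates 4 to 6, so in every comparison with HIIT the batch term leaves the estimate to the 3 HIIT libraries of batch 1. For some of the genes described below, calls that end, directions that turn and values that move by over 1.5 times without the term are stated, not always with the value. The standard error of a log2 fold change was taken as its size over the square root of F. CPM values are scaled by TMM, and log2 CPM used a prior count of 2. The groups, comparisons, tests, alternative settings, gene lists tested with camera and the rule for named genes were fixed before the data were examined.

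Lists of genes for muscle metabolism, fibre types, stress, epigenetic and microRNA machinery and cell types were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of the 34 fixed lists 33 had measured members, and the microRNA gene records made 1 more. Over 8 comparisons 77 of 272 such tests passed, and 0 held with an estimated correlation, where the lowest adjusted p was 0.0627. By fry, which does not compare a list with other genes, 7 lists passed in HIIT vs control, 5 in HIIT plus inhibitor vs control, 2 vs HIIT, 3 vs inhibitor, 6 in lactate vs HIIT, 2 in the interaction and none in lactate vs control or inhibitor vs control (7 lists in each at an unadjusted p under 0.05, where camera passed 2 and 14). Every passing list had its median, mean and test in 1 direction, and no median changed sign under RLE scaling or without scaling, although without scaling 8 of the 77 came over 1.5 times closer to 0 and 2 went as much farther from it. Named genes were, for each comparison, the lactate genes Slc16a1, Slc16a7, Slc16a3, Ldha and Ldhb and Ppargc1a whatever their values, up to 10 risen and 10 fallen genes with the smallest p among those past the threshold (without predicted genes and Riken clones, and the 3 nearest where none passed), and up to 4 members with the smallest p of each list that passed or held a called gene. Some named genes have exons opposite another gene that holds counts, and reads of such pairs cannot be told apart without strand: these include Rasip1 (A030001D20Rik, whose counts come to 8.14% of its own), Piezo1 (Ctu2, 22.7%), Rps6kb1 (Rnft1, 125%), Dgcr8 (Trmt2a, 48.8%), Dbp (Sphk2, 184%) and Nr1d1 (Thra, 805%), and their values are uncertain to that extent, as are those of genes with near-identical copies.

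The fit was tested on simulated data first for 4 of the comparisons. Among genes changed by 1.5, 2 and 4 times, lactate vs control recovered 35.8, 64.2 and 95.5% (8875 genes tested), HIIT vs control 16.4, 56.7 and 92.4% (8905), inhibitor vs control 23.9, 65.7 and 100% (8877), and HIIT plus inhibitor vs inhibitor 34.3, 85.1 and 97.0% (8881). Camera passed 3.5% of 200 unshifted lists (8869 genes).

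The settings fixed then were DESeq2 1.42.0, limma-voom with sample weights, RLE or no scaling, no low-count filter or a mean of at least 5 CPM, no robust step, no batch term, batch 1 alone, replicate number as a block, mitochondrial genes left out, only the compared groups, and each library left out. Added after the data were seen were log2 total count as a covariate, thinning to the shallowest library, trends with GC content or length taken out, leaving out libraries under 700000 counts, and the list tests without each library. Comparisons sharing the 4 controls were set beside 20 simulations of unchanged groups and beside splits of the controls into 2 and 2. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.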

Results

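Gene expression was measured in the gastrocnemius, the large calf muscle, of male BALB/c mice after 6 weeks of treatment or training. The 28 libraries fell into 5 groups. There were 4 from control mice injected with PBS, 6 from mice injected with lactate at 500 mg/kg, and 6 from mice trained by high-intensity interval training (HIIT) on a treadmill. A further 6 came from mice given an inhibitor of the lactate transporters MCT1 and MCT2, and 6 from mice given HIIT and the inhibitor together. The design addresses whether injected lactate brings muscle RNA toward the state seen after training, and whether blocking lactate transport alters the training state. HIIT replicates 1 to 3 were sequenced in batch 1 with every other group, while HIIT replicates 4 to 6 alone formed batch 2. Total counts per library ran from 993438 to 1167078 in control, 527692 to 946554 in lactate, 632386 to 931203 in batch 1 HIIT, and 1163218 to 1256057 in batch 2 HIIT. They ran from 767267 to 1133713 in the inhibitor group and 700212 to 1011554 in HIIT plus inhibitor. At these depths the detection floor of 3 counts lay between 2.39 and 5.69 CPM (counts scaled to library size), for counting error only. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, part of which may be technical. Below, levels are mean CPM ± SD over the libraries of a group, and log2 fold changes carry their standard error.

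The first principal component of log2 CPM (27.2% of the variance) set batch 2 HIIT, at 57.3 to 68.1, apart from the other 25 libraries, at -13.1 to 2.36. On the second component (10.7%), control (11.6 to 30.0) and inhibitor libraries (9.08 to 20.1) lay apart from lactate (-23.8 to -6.01), HIIT plus inhibitor (-11 to 6.77) and batch 1 HIIT (-23.4 to 2.09).

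**Figure D1:**
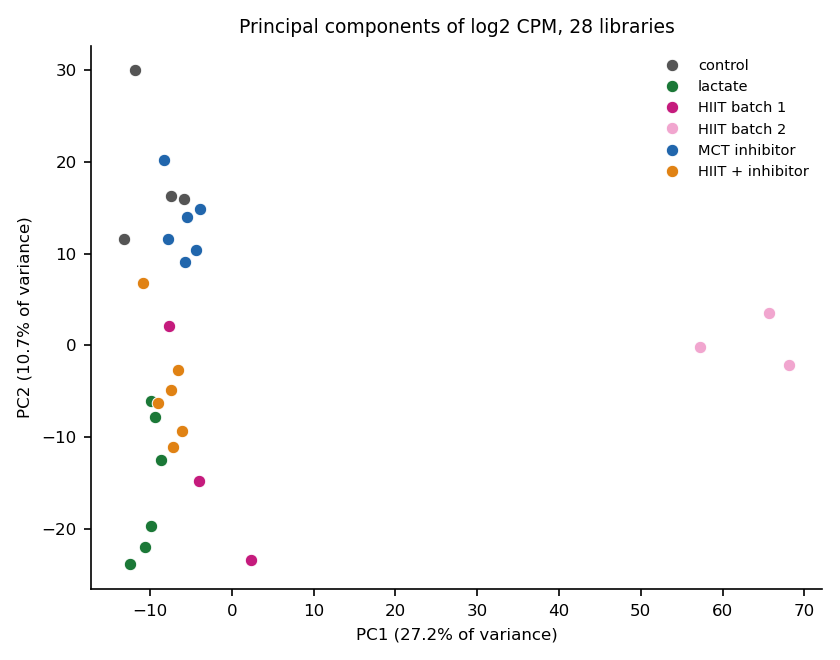
Scores of the 28 libraries on the first (x axis, 27.2% of variance) and second (y axis, 10.7%) principal components of log2 CPM, 1 point per library, coloured by group with the HIIT batches apart. Batch 2 HIIT lies apart at 57.3 to 68.1 on the x axis.

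Of the genes that carry and convert lactate, Slc16a3 fell in lactate and Ldha rose in batch 1 HIIT. Slc16a1 (GRCm39 chromosome 3, 104545980 to 104565778), which encodes MCT1, one of the inhibitor's targets, averaged 42.2 ± 8.73 CPM in control, 50.1 ± 7.69 in lactate, 55.9 ± 8.13 in batch 1 HIIT, 47.1 ± 8.43 with the inhibitor and 57.1 ± 7.52 with HIIT plus inhibitor. It passed in no comparison with the batch term (lactate vs control log2 fold change 0.25 ± 0.17, adjusted p = 0.356), and in HIIT vs control without it (0.46). Slc16a3 (chromosome 11, 120839310 to 120849826), which encodes MCT4, fell in lactate to 357 ± 35.8 from 506 ± 119.7 CPM (log2 fold change -0.50 ± 0.13, adjusted p = 0.00576, below the control mean in 6 of 6 libraries). Its direct difference between lactate and HIIT was -0.56 ± 0.14 and did not pass (adjusted p = 0.0506), while it passed without the batch term (-0.59). Ldha (chromosome 7, 46491698 to 46505051), the muscle-type lactate dehydrogenase subunit, rose in batch 1 HIIT to 2574 ± 164 from 1940.0 ± 267 CPM (0.41 ± 0.12, adjusted p = 0.0385). Ldha stood at 1376 ± 188 in batch 2 HIIT, and without the batch term the fold change was 0.02 and did not pass. Ldhb (chromosome 6, 142435975 to 142453683), the heart-type subunit, averaged 145 ± 18.5 CPM in control, 74.5 ± 24.9 in lactate, 98.3 ± 90.8 in batch 1 HIIT, 99.8 ± 36.2 with the inhibitor and 139.8 ± 52.6 with HIIT plus inhibitor. It did not pass in any comparison with control (lactate -0.94 ± 0.42, adjusted p = 0.14). Ppargc1a (chromosome 5, 51611591 to 52273316), which encodes PGC-1alpha, a coactivator of mitochondrial biogenesis, averaged 86.6 ± 97.7 CPM in batch 1 HIIT and 38.0 ± 5.50 in control (1.18 ± 0.49, adjusted p = 0.159, not passed). It rose in batch 2 over batch 1 (1.59 ± 0.46, adjusted p = 0.00805), and over both batches without the batch term its HIIT vs control difference was 2.21 and passed. So did its differences in lactate vs HIIT (-2.20), HIIT plus inhibitor vs HIIT (-1.90) and the interaction (-2.27) without that term. Slc16a7, which encodes MCT2, had 2 to 13 counts per group in all and was too low to test. The Slc16a3 call was lost without control 1, with a depth covariate or without the libraries under 700000 counts. In Slc16a3, 377 exonic bases lie opposite Csnk1d, whose counts came to 13.7% of its own.

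**Figure D2:**
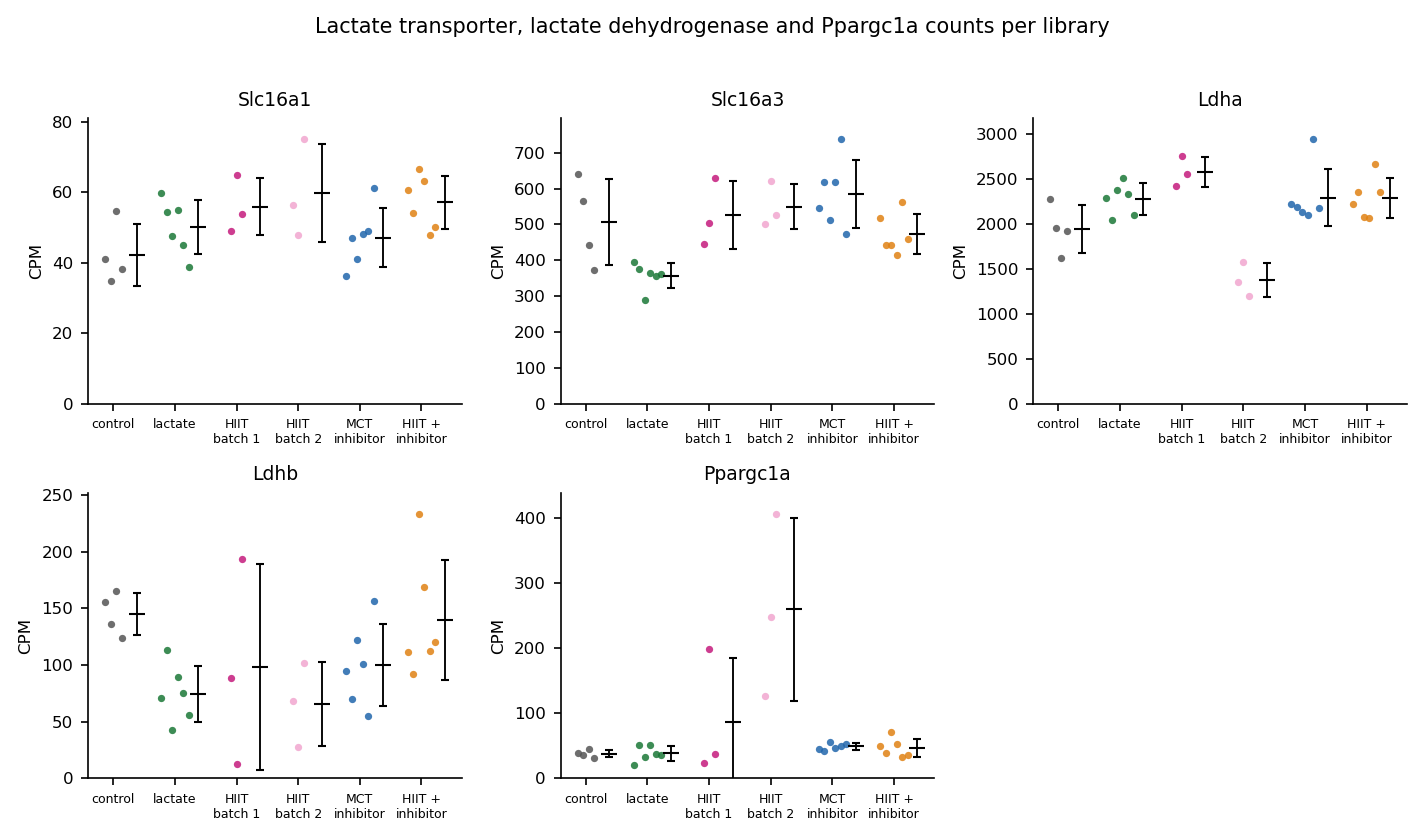
Normalised expression (y axis, CPM) of Slc16a1, Slc16a3, Ldha, Ldhb and Ppargc1a in each group (x axis, HIIT batches apart), 1 point per library with the mean and SD in black. Ppargc1a spreads widely within HIIT, with means of 86.6 CPM in batch 1 and 259.9 CPM in batch 2 against 38.0 CPM in control.

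Lactate injection was compared with PBS injection. In lactate, 609 genes rose and 682 fell of 9110 tested (2585 at an unadjusted p under 0.05). Acyp2 (GRCm39 chromosome 11, 30455991 to 30599778), which encodes an acylphosphatase of muscle, rose to 277 ± 32.0 CPM (n = 6) from 86.8 ± 32.9 (n = 4; log2 fold change 1.66 ± 0.16, adjusted p = 5.05e-09). Sdhd (chromosome 9, 50507640 to 50515149), a membrane subunit of succinate dehydrogenase, rose to 233 ± 49.4 from 83.6 ± 32.6 CPM (1.45 ± 0.20, adjusted p = 1.32e-05). Atf4 (chromosome 15, 80139385 to 80141746), the transcription factor of the integrated stress response, fell to 608 ± 50.5 from 1275 ± 127 CPM (-1.07 ± 0.10, adjusted p = 1.11e-09). Rasip1 (chromosome 7, 45276961 to 45288516), a Ras-binding protein of vessel endothelium, fell to 21.4 ± 4.08 from 78.4 ± 15.0 CPM (-1.85 ± 0.19, adjusted p = 3.11e-09). Among the other named genes, Mrps28, a mitochondrial ribosome subunit (1.26 ± 0.18), and Scn4b, a sodium channel subunit (0.85 ± 0.12), rose. Kctd2 (-1.38 ± 0.14), the complex I gene Ndufa5 (-1.05 ± 0.12) and Prkag1, a subunit of the energy sensor AMPK (-1.28 ± 0.15), fell. The 20 genes picked by smallest p, 10 in each direction, lay on the same side of the control mean in 6 of 6 lactate libraries.

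Of the 26 extracellular matrix genes measured, 5 rose and 21 did not pass, with 9 risen when adjusted over the list alone. Their median log2 fold change was 0.55 (camera adjusted p = 0.00236, and adjusted p = 0.892 with an estimated correlation). Dcn, decorin (0.50 ± 0.10, adjusted p = 0.000532), and Loxl1, a collagen cross-linking enzyme (0.97 ± 0.24, adjusted p = 0.00455), were among them. Lactate 2 and 3 scored 1.05 and 0.911 on the list and the other 4 from -0.194 to 0.284 (control -0.732 to 0.274). Fibroblast and tendon markers went both ways: 4 of 13 rose, 2 fell and 7 did not pass, 5 and 2 adjusted over the list alone (camera adjusted p = 0.162), with Dpt, dermatopontin, up (0.79 ± 0.16) and the tendon transcription factor Scx down (-1.17 ± 0.27). Of 6 Schwann cell markers 3 fell, Mpz among them (-0.82 ± 0.28), and 3 did not pass, 4 down over the list alone (camera adjusted p = 0.162), and both neutrophil markers fell (0.162). Of 10 smooth muscle markers 2 rose, 1 fell and 7 did not pass, the same over the list alone (0.86). The 15 slow fibre genes had a median of -0.80 (camera adjusted p = 0.0141, and adjusted p = 0.892 with an estimated correlation). No slow fibre member passed by edgeR or DESeq2, 1 passed by limma-voom, and 4 had an unadjusted p under 0.05. Myh7, the slow myosin heavy chain, averaged 57.1 ± 10.5 against 153 ± 43.6 CPM (-1.41 ± 0.54, adjusted p = 0.0862). Of 21 fast fibre genes, 5 rose and 16 did not pass, the same adjusted over the list alone, with Myl1 (0.59 ± 0.12) among the risen. Among 63 nuclear oxidative phosphorylation genes, 10 rose, 6 fell and 47 did not pass, 12 up and 9 down adjusted over the list alone. Of 9 mitochondrially encoded genes, 3 rose, led by ND1 (0.67 ± 0.12, adjusted p = 8.25e-05), and 6 did not pass, 3 up and 1 down adjusted over the list alone. Glycolysis and glycogen genes went both ways (4 rose, 3 fell, 16 did not pass, 4 and 4 adjusted over the list alone). Pfkfb3, an activator of glycolysis, rose (1.76 ± 0.33, adjusted p = 0.000799). Gys1, glycogen synthase (-0.74 ± 0.13, adjusted p = 9.56e-05), and Pgam2, the muscle phosphoglycerate mutase (-0.80 ± 0.16, adjusted p = 0.000719), fell. In the list of lactate transport and use, 3 of 18 rose, 1 fell and 14 did not pass, the same adjusted over the list alone. Pdhb, a subunit of pyruvate dehydrogenase (0.55 ± 0.11, adjusted p = 0.00042), and Pdk4, a kinase that inhibits that enzyme, rose (137 ± 92.5 against 19.2 ± 9.61 CPM, 2.80 ± 0.63, adjusted p = 0.00445). The count was 803 without control 1, 640 without the batch term, 449 without the libraries under 700000 counts and 200 with a depth covariate. That covariate also ended the slow fibre call (adjusted p = 0.105), and without the batch term Pdhb, ND1 and Mpz no longer passed. Both list calls were lost without control 2 (adjusted p = 0.0618 for each). Acyp2, Sdhd, Atf4, Rasip1, Kctd2 and Gys1 passed under each of these and with each single library left out.

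HIIT was compared with control through the 3 batch 1 HIIT libraries, because the batch term leaves the batch 2 libraries only to estimate the batch. In HIIT, 290 genes rose and 249 fell (1976 at an unadjusted p under 0.05). The split was 170 up and 414 down with no scaling beyond the total count. Pdk4 (GRCm39 chromosome 6, 5483351 to 5496278) rose to 439 ± 113 CPM (n = 3) from 19.2 ± 9.61 (n = 4; log2 fold change 4.49 ± 0.66, adjusted p = 0.00032). Acyp2 rose to 228 ± 10.5 from 86.8 ± 32.9 CPM (1.38 ± 0.19, adjusted p = 1.86e-05). Rasip1 fell to 18.1 ± 2.98 from 78.4 ± 15.0 CPM (-2.08 ± 0.25, adjusted p = 6.1e-07) and Atf4 to 751 ± 80.3 from 1275 ± 127 CPM (-0.76 ± 0.12, adjusted p = 0.00017). Ucp3, an uncoupling protein of muscle mitochondria, rose to 128 ± 30.3 from 29.1 ± 15.4 CPM (2.14 ± 0.38, adjusted p = 0.00177). The glycolytic enzyme gene Tpi1 rose (0.68 ± 0.12, adjusted p = 0.000297), as did Trip10 (1.02 ± 0.18) and Mrps28 (1.42 ± 0.21). Kctd2 (-1.36 ± 0.17) and Grn, progranulin (-1.04 ± 0.17), fell. All of these lay on one side of the control mean in 3 of 3 libraries. Without the batch term, over 6 HIIT libraries, the fold changes were 4.33 for Pdk4, 0.94 for Acyp2, -1.31 for Rasip1, -0.94 for Atf4 0.62 for Trip10 and 0.31 for Tpi1, of which Tpi1 no longer passed.

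Among 18 glucocorticoid response genes, 4 rose and 14 did not pass, with 5 risen adjusted over the list alone (camera adjusted p = 5.25e-05, and adjusted p = 0.389 with an estimated correlation). Those that rose were Pdk4, the metallothionein genes Mt1 (2.41 ± 0.61) and Mt2 (3.07 ± 0.80), and Angptl4, an inhibitor of lipoprotein lipase (2.90 ± 0.86), each of which other signals induce too. Of 23 genes of glycolysis and glycogen, 6 rose, 1 fell and 16 did not pass, with 9 up and 2 down when adjusted over the list alone (camera adjusted p = 0.00053, and adjusted p = 0.389 with an estimated correlation). Pfkm, muscle phosphofructokinase (0.44 ± 0.11, adjusted p = 0.0114), and Agl, the glycogen debranching enzyme (0.58 ± 0.14), were among the risen. Fast fibre genes shared that direction, with Myl1 (0.65 ± 0.14) and the calcium pump gene Atp2a1 (0.55 ± 0.13) up. Of 21, 5 rose and 16 did not pass, 8 up adjusted over the list alone (camera adjusted p = 0.000951, and adjusted p = 0.389 with an estimated correlation). The median of the 15 slow fibre genes was -0.47 (camera adjusted p = 0.0395, and adjusted p = 0.704 with an estimated correlation). No member passed by edgeR or limma-voom, 1 passed by DESeq2 and 1 had an unadjusted p under 0.05. The 3 libraries' mean scores ran from -1.24 to 0.866. This call was lost without HIIT 1 (-0.22), HIIT 2 (-0.05), control 2 (-0.32) or control 4 (-0.43), and the median was -1.51 without HIIT 3. In the list of mitochondrial biogenesis and exercise regulators, 5 of 28 rose and 23 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.389 with an estimated correlation). The risen genes included Mstn, myostatin (1.25 ± 0.26), and the exercise-induced nuclear receptor gene Nr4a1 (2.00 ± 0.41). With them were Prkaa2, the AMPK catalytic subunit (0.57 ± 0.14), and Esrra, a nuclear receptor of mitochondrial genes (0.68 ± 0.17). Of 23 atrophy and proteolysis genes, 3 rose, 1 fell and 19 did not pass, 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.389 with an estimated correlation). Those risen were Mt1, Mt2 and Bnip3, a mitophagy receptor. Of 18 genes of lactate transport and use, 3 rose and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0281, and adjusted p = 0.389 with an estimated correlation). The 3 were Pdk4, Ldha and Pdp2, a phosphatase that activates pyruvate dehydrogenase (1.07 ± 0.31). Markers of other cell types moved too. Of 6 nerve and Schwann cell markers, 3 fell and 3 did not pass, 5 down adjusted over the list alone (median -1.33, camera adjusted p = 0.000179, and adjusted p = 0.323 with an estimated correlation). Mpz, the main peripheral myelin protein, was among the fallen (-1.57 ± 0.38, adjusted p = 0.00955). Of 13 endothelial markers, 3 fell (Egfl7, Emcn and Kdr) and 10 did not pass, 4 down adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.389 with an estimated correlation). The count was 2274 without the batch term, 335 without control 1, 146 without HIIT 2 and 100 with a depth covariate. Of the 9 passing lists, 8 were lost without the batch term (adjusted p = 0.0521 to 0.990, where lactate transport and use turned downward), and 6 with the depth covariate (0.0702 to 0.247). Of single members Pfkm (0.05), Esrra (0.34), Myl1 (0.26), Kdr (-0.41) and Mpz (-0.35) no longer passed without that term, and Bnip3 turned from 0.39 to -0.13. Single libraries ended the endothelial (without HIIT 2), lactate transport (HIIT 3 or control 4), mitochondrial biogenesis (HIIT 3) and atrophy (control 4) calls too, at adjusted p = 0.0616 to 0.176.

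The inhibitor alone was compared with control. Here 11 genes rose and 4 fell (953 at an unadjusted p under 0.05), and with no scaling beyond the total count 5 rose and 8 fell. Trip10, an adaptor in insulin-stimulated glucose transport, rose (log2 fold change 0.77 ± 0.15, adjusted p = 0.0171), as did Lsmem1 (1.14 ± 0.23). Acyp2 rose to 153 ± 28.4 from 86.8 ± 32.9 CPM (n = 6 and 4, 0.80 ± 0.16, adjusted p = 0.0318), along with Mrps28 (0.86 ± 0.18), Sdhd (0.99 ± 0.20) and Scn4b (0.52 ± 0.12). Also risen were the mechanosensitive channel gene Piezo1 (0.91 ± 0.20), the S6 kinase gene Rps6kb1 (0.66 ± 0.14) and Crispld2 (0.58 ± 0.13). Tmem50a (-0.59 ± 0.11, adjusted p = 0.0171), Tmem176a (-1.02 ± 0.19), Lrpprc (-0.59 ± 0.13), and the ribosomal protein gene Rpl13a (-0.56 ± 0.12), whose reads pseudogenes can share, fell. Each was on its side of the control mean in 6 of 6 libraries.

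The gene lists showed shifts that few single members carried. Fast fibre genes had a higher median (0.19) and slow fibre genes a lower one (-0.60), each at a camera adjusted p = 2.19e-05. Both had adjusted p = 0.353 with an estimated correlation. Adjusted over the list alone, 4 of 21 fast fibre genes rose and 2 of 15 slow fibre genes fell. No member of either passed over all genes by edgeR, DESeq2 or limma-voom, with 8 and 2 members at an unadjusted p under 0.05. The slow fibre scores of the 6 inhibitor libraries spread from -1.86 to 0.627, against 0.225 to 0.628 in control. Higher medians, with their camera adjusted p, were those of glycolysis (0.23, adjusted p = 0.000174), extracellular matrix (0.21, adjusted p = 0.000686), immediate early (0.30, adjusted p = 0.00207), glucocorticoid response (0.27, adjusted p = 0.00232) and mitochondrial biogenesis (0.15, adjusted p = 0.00388) genes. These had adjusted p = 0.353 to 0.465 with an estimated correlation. Lower medians were those of fatty acid oxidation (-0.21, adjusted p = 0.000181), ribosomal protein (-0.13, adjusted p = 0.000306) and adipocyte (-0.86, adjusted p = 0.000613) genes. Also lower were interferon (-0.26, adjusted p = 0.00756), Schwann cell (-0.34, adjusted p = 0.00786), neutrophil (-2.67, adjusted p = 0.0263) and cholesterol synthesis (-0.27, adjusted p = 0.0263) genes. The lower lists had adjusted p = 0.353 to 0.401 with an estimated correlation, and a depth covariate ended the cholesterol call (adjusted p = 0.0669). Among these lists, 1 fatty acid gene and both neutrophil genes fell and 1 extracellular matrix gene rose when adjusted over the list alone. Of 63 nuclear oxidative phosphorylation genes Sdhd alone passed, with 1 up and 1 down adjusted over the list alone. The 15 calls fell to 0 without control 1 (946 at an unadjusted p under 0.05), 0 without the batch term (603) and 0 after thinning (712), where DESeq2 and limma-voom gave 52 and 29 on the full data. They numbered 1 without inhibitor library 5, 2 without control 2 or 4, 4, 6 and 9 without inhibitor libraries 3, 2 and 1, 27 over the compared groups alone and 81 with no low-count filter. List calls lost without 1 library were those of matrix (control 2, median 0.09), glucocorticoid (control 1 or 4, 0.09 and 0.13), interferon (control 2 or 4), Schwann cell (control 1 or 3), cholesterol (control 2, at -0.15, control 3 or inhibitor 6) and neutrophil genes (control 2, at -1.33, control 3, inhibitor 1 or 5). Their adjusted p ran from 0.0508 to 0.214, and of the kept calls the slow fibre median was -0.39 without control 2 and the ribosomal one -0.08 without inhibitor 3. Matrix was at 0.32 without control 4, and glucocorticoid at 0.49 and 0.14 without control 2 and inhibitor 3.

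HIIT with the inhibitor was compared with control. Here 255 genes rose and 405 fell (1951 at an unadjusted p under 0.05). Acyp2 rose to 222 ± 29.3 from 86.8 ± 32.9 CPM (n = 6 and 4; log2 fold change 1.34 ± 0.16, adjusted p = 9.07e-07). Pdk4 rose to 179.8 ± 58.0 from 19.2 ± 9.61 CPM (3.19 ± 0.62, adjusted p = 0.00226). Rasip1 (-1.60 ± 0.18, adjusted p = 1.24e-07) and Atf4 (742 ± 104 against 1275 ± 127 CPM, -0.78 ± 0.10, adjusted p = 1.33e-06) fell. So did Dync1h1, the heavy chain of the dynein motor (-1.15 ± 0.14, adjusted p = 2.12e-07) and Grn (-0.95 ± 0.13). Sdhd rose (1.31 ± 0.20), and all of these had 6 of 6 libraries on their side of the control mean. Of 20 heat shock and unfolded protein response genes, 5 fell and 15 did not pass, 7 down adjusted over the list alone (median -0.35, camera adjusted p = 0.00273, and adjusted p = 0.481 with an estimated correlation). They included Hspa5, the main chaperone of the endoplasmic reticulum (-0.47 ± 0.10, adjusted p = 0.00232), and the cytosolic cochaperone gene Dnaja1 (-0.59 ± 0.16). Schwann cell markers were lower (median -0.78, camera adjusted p = 0.00273, and adjusted p = 0.292 with an estimated correlation). Of 6, 2 fell (Mpz at -1.34 ± 0.28 and S100b at -1.63 ± 0.41) and 4 did not pass, 3 down adjusted over the list alone. In lactate transport and use, 2 of 18 rose and 16 did not pass, 5 up adjusted over the list alone (median 0.19, camera adjusted p = 0.00596, and adjusted p = 0.251 with an estimated correlation). The 2 were Pdk4 and Mpc1, a subunit of the mitochondrial pyruvate carrier (0.47 ± 0.11, adjusted p = 0.00398). Of 28 mitochondrial biogenesis genes 2 rose, Esrra (0.58 ± 0.14) and Prkaa2 (0.46 ± 0.12), and 26 did not pass, 3 up adjusted over the list alone. Their median was 0.23 (camera adjusted p = 0.0179, and adjusted p = 0.481 with an estimated correlation). The count was 329 without control 1, 252 without the batch term and 272 with a depth covariate, under which the mitochondrial biogenesis list was lost (adjusted p = 0.111), as it was without HIIT plus inhibitor 3 (median 0.15) or control 2 (0.0539 and 0.0945). It was at 0.37 without HIIT plus inhibitor 6, and heat shock at -0.18 without control 3. Hspa5, Dnaja1, Mpz, S100b, Mpc1, Esrra and Prkaa2 did not pass without the batch term, at folds within 0.01 of those given. In contrast, Acyp2, Pdk4, Rasip1, Atf4, Sdhd and Dync1h1 passed in each setting and without each single library.

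**Figure D3:**
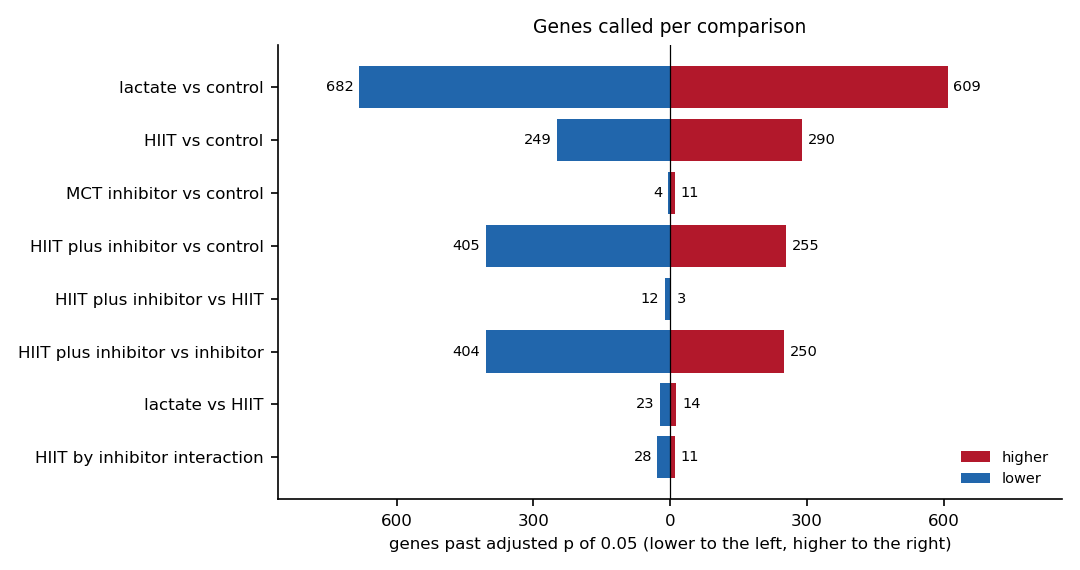
Genes called at an adjusted p under 0.05 in each of 8 comparisons (y axis; edgeR, 9110 genes tested), with risen genes drawn to the right and fallen genes to the left of 0 on the x axis. Lactate vs control has 609 up and 682 down, and the inhibitor alone vs control 11 up and 4 down.

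**Figure D4:**
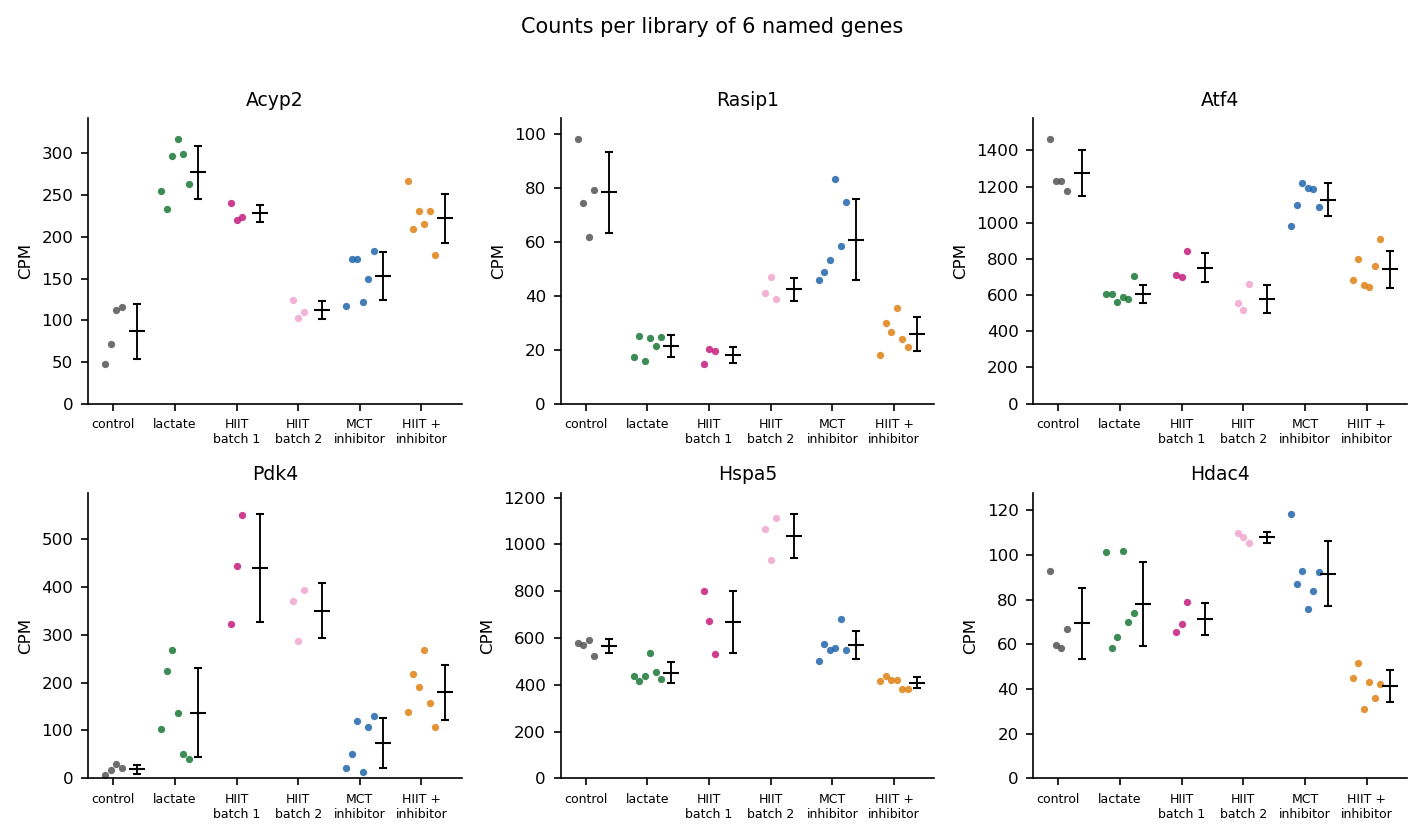
Normalised expression (y axis, CPM) of Acyp2, Rasip1, Atf4, Pdk4, Hspa5 and Hdac4 by group (x axis, HIIT batches apart), 1 point per library with the mean and SD in black. Atf4 averages 1275 CPM in control and 608 in lactate, and Acyp2 86.8 and 277.

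Trained mice with and without the inhibitor were set side by side, the HIIT side resting on the batch 1 libraries. With the inhibitor 3 genes rose and 12 fell (1047 at an unadjusted p under 0.05), or 6 and 8 with no scaling beyond the total count. Hspa5 (GRCm39 chromosome 2, 34662102 to 34666541), the endoplasmic reticulum chaperone BiP, fell to 409 ± 22.3 CPM (n = 6) from 668 ± 134 (n = 3; log2 fold change -0.70 ± 0.11, adjusted p = 0.000855). Its fold change was -1.06 without the batch term. Mylk4, a myosin light chain kinase (-0.79 ± 0.15, adjusted p = 0.0199), the amino acid transporter gene Slc38a2 (-1.23 ± 0.23), and Noct, nocturnin (-0.98 ± 0.21), fell also. Nfatc2, a calcium-regulated transcription factor, rose (48.6 ± 7.96 against 21.1 ± 1.78 CPM, 1.19 ± 0.24, adjusted p = 0.0199), as did Akap8 (1.07 ± 0.24) and Mxra7 (1.46 ± 0.33). All lay beyond the HIIT mean in 6 of 6 libraries. Of 20 heat shock and unfolded protein response genes, 2 fell (Hspa5, and Dnaja1 at -0.86 ± 0.18) and 18 did not pass, 10 down adjusted over the list alone. Their median was -0.50 (camera adjusted p = 1.03e-08, and adjusted p = 0.0959 with an estimated correlation). Lower medians, with their camera adjusted p, were those of glucocorticoid response (-0.48, adjusted p = 3.19e-05), glycolysis (-0.23, adjusted p = 0.000161), fast fibre (-0.19, adjusted p = 0.0011), immediate early (-0.50, adjusted p = 0.00259) and atrophy (-0.08, adjusted p = 0.0219) genes. The atrophy median was -0.0056 with no scaling, which raised the median of all genes by 0.0789. The same 5 lists had adjusted p = 0.337 to 0.406 with an estimated correlation. Adjusted over the list alone 4 of 18 glucocorticoid, 6 of 23 glycolysis, 5 of 18 immediate early and 5 of 23 atrophy genes fell. Higher medians were those of slow fibre (0.62, adjusted p = 2.07e-05), DNA methylation (0.16, adjusted p = 0.0281), angiogenesis (0.17, adjusted p = 0.0348) and interferon (0.33, adjusted p = 0.0393) genes. So were those of endothelial (0.44, adjusted p = 0.000605), fibroblast (0.44, adjusted p = 0.0219) and adipocyte (0.64, adjusted p = 0.0237) markers. These 7 had adjusted p = 0.17 to 0.502 with an estimated correlation. Adjusted over the list alone 3 of 19 DNA methylation genes, 2 of 13 endothelial markers and 1 of 15 angiogenesis genes rose. The count was 2048 without the batch term, where 9 of the 13 passing lists were lost (adjusted p = 0.0800 to 0.897, at which glycolysis turned upward) and Akap8 (0.33), Dnaja1 (-0.48) and Noct (-0.58) no longer passed, with Mxra7 at 0.73. HIIT 2 stood apart on immediate early genes, with a score of 1.09 (HIIT 1 and 3 at -0.068 and -0.246). Without it the medians were -0.09 for these, 0.06 for angiogenesis, 0.23 for endothelial, 0.13 for fibroblast, 0.42 for adipocyte and -0.09 for atrophy genes, all 6 lost (adjusted p = 0.181 to 0.688). Kept calls had medians of -0.11 for fast fibre, 0.26 for slow fibre, -0.28 for glucocorticoid, 0.06 for DNA methylation and 0.57 for interferon genes there. Without HIIT 3 the immediate early (-0.81), glucocorticoid (-0.74), slow fibre (1.83), endothelial (0.68), fibroblast (0.73) and adipocyte (1.16) medians were larger. Further losses (adjusted p = 0.0519 to 0.21) were DNA methylation (HIIT 1 or 3, HIIT plus inhibitor 5), interferon (HIIT 1 or 3, HIIT plus inhibitor 3 or 5), angiogenesis (HIIT plus inhibitor 2, 3 or 4), fibroblast (HIIT 1, HIIT plus inhibitor 6), adipocyte (HIIT 1) and atrophy (HIIT plus inhibitor 6). The atrophy median was -0.24 without HIIT 1 and -0.04 and -0.13 without HIIT plus inhibitor 1 and 2, that of angiogenesis 0.10 without HIIT plus inhibitor 1, and that of fibroblast markers 0.24 without HIIT plus inhibitor 6. The count was 1 without HIIT 2 or HIIT plus inhibitor 4, 2 without HIIT plus inhibitor 6, 100 without HIIT 3, 33 and 41 without HIIT 4 and 5, 9 with a depth covariate and 116 with no filter.

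Training on the inhibitor background was read from HIIT plus inhibitor against inhibitor alone, both in batch 1. Here 250 genes rose and 404 fell (1990 at an unadjusted p under 0.05). Crispld2 (GRCm39 chromosome 8, 120719177 to 120779533), a secreted glycoprotein, fell to 79.4 ± 15.0 from 182 ± 24.8 CPM (n = 6 and 6; log2 fold change -1.20 ± 0.12, adjusted p = 9.19e-09). Hdac4 (chromosome 1, 91856501 to 92123424), a histone deacetylase, fell to 41.4 ± 7.14 from 91.7 ± 14.5 CPM (-1.14 ± 0.15, adjusted p = 3.53e-06). Mylk4 (-0.91 ± 0.13), Rasip1 (-1.23 ± 0.17), Atf4 (-0.60 ± 0.09) and the clock output gene Tef (-0.99 ± 0.14) fell. Bnip3 (0.54 ± 0.09) and the lysosomal protease gene Ctsl (0.63 ± 0.11) rose. Each lay on its side of the inhibitor mean in 6 of 6 libraries. Of 28 fatty acid oxidation genes 4 rose and 24 did not pass, 5 up adjusted over the list alone (median 0.27, camera adjusted p = 0.000988, and adjusted p = 0.614 with an estimated correlation). Acsl1, an acyl-CoA synthetase (0.57 ± 0.11), and Cd36, a fatty acid carrier (0.61 ± 0.15), rose. Of 63 nuclear oxidative phosphorylation genes 4 rose, 1 fell and 58 did not pass, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.00264, and adjusted p = 0.646 with an estimated correlation). Of 15 slow fibre genes 1 rose, Sln, sarcolipin (1.96 ± 0.49, adjusted p = 0.0169), and 14 did not pass, 5 up adjusted over the list alone. Their median was 0.88 (camera adjusted p = 9.23e-06, and adjusted p = 0.524 with an estimated correlation). Of 21 fast fibre genes 1 fell and 20 did not pass, the same adjusted over the list alone (median -0.09, camera adjusted p = 0.0473, and adjusted p = 0.63 with an estimated correlation), a call lost without the batch term (adjusted p = 0.101). Of 20 heat shock genes 5 fell, Dnaja1 among them (-0.70 ± 0.15), and 15 did not pass, 11 down adjusted over the list alone. Their median was -0.36 (camera adjusted p = 0.000989, and adjusted p = 0.524 with an estimated correlation). Of 18 immediate early genes 4 fell and 14 did not pass, 6 down adjusted over the list alone. Jun (-0.50 ± 0.14), Jund (-0.56 ± 0.15), Fosl2 (-0.65 ± 0.20) and Ier3 (-0.80 ± 0.22) were the fallen ones. The list's median was -0.57 (camera adjusted p = 0.00266, and adjusted p = 0.541 with an estimated correlation). In the extracellular matrix 2 of 26 fell, Serpinh1 among them (-0.74 ± 0.16), and 24 did not pass, 6 down adjusted over the list alone. Matrix genes had a median of -0.38 (camera adjusted p = 0.00304, and adjusted p = 0.63 with an estimated correlation). Angiogenesis (median 0.22, camera adjusted p = 0.0147; 2 of 15 rose, 13 did not pass, the same adjusted over the list alone) and interferon genes (0.27, camera adjusted p = 0.0183) were higher. Both had adjusted p = 0.524 with an estimated correlation. Adipocyte markers were higher beside the fatty acid genes (median 0.72, camera adjusted p = 0.00264, and adjusted p = 0.541 with an estimated correlation), with 1 of 11 up adjusted over the list alone. The count was 1005 by limma-voom and 247 without the batch term, where Bnip3, Jun, Jund, Fosl2, Ier3 and Serpinh1 no longer passed. Fast fibre was lost in 8 of the 12 fits without 1 library (adjusted p up to 0.137; medians -0.06 and -0.17 without HIIT plus inhibitor 3 and 5), interferon without inhibitor 2 (0.0527), and oxidative phosphorylation without HIIT plus inhibitor 6 (0.0745) or inhibitor 1 (0.0531, median 0.06). Interferon was at 0.48 without inhibitor 4, and fatty acid oxidation at 0.17 without HIIT plus inhibitor 3.

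Whether the HIIT difference itself changed with the inhibitor was tested as an interaction. A negative value means a smaller or more negative HIIT effect under the inhibitor. The interaction passed for 11 genes upward and 28 downward (1247 at an unadjusted p under 0.05), or 18 and 13 with no scaling beyond the total count, which moved the median gene by 0.115. Mylk4 (GRCm39 chromosome 13, 32884807 to 32967947) had the smallest p (interaction log2 fold change -1.33 ± 0.21, adjusted p = 0.00278). It averaged 1019 ± 178 CPM in control, 1365 ± 240.3 in batch 1 HIIT, 1481 ± 110.5 with the inhibitor and 791 ± 106 with both. Hdac4 (-1.20 ± 0.24, adjusted p = 0.0216), Hspa5 (-0.71 ± 0.15, adjusted p = 0.0299), Piezo1 (-1.46 ± 0.30), Slc38a2 (-1.64 ± 0.31) and Nr4a1 (-2.57 ± 0.52) were negative. Akap8 (1.64 ± 0.29, adjusted p = 0.00459), Ndrg1 (1.10 ± 0.26) and Nfatc2 (1.25 ± 0.31) were positive. Of 23 glycolysis genes 3 were lower (Pfkm -0.62 ± 0.14, Tpi1 -0.63 ± 0.15, Pgm1 -0.68 ± 0.17) and 20 did not pass, 13 lower adjusted over the list alone. Their median was -0.47 (camera adjusted p = 2.16e-07, and adjusted p = 0.199 with an estimated correlation). Fast fibre genes shared the direction (median -0.46, camera adjusted p = 2.16e-07, and adjusted p = 0.247 with an estimated correlation), 13 of 21 lower adjusted over the list alone. Slow fibre genes had the opposite one (median 1.23, camera adjusted p = 7.27e-09, and adjusted p = 0.252 with an estimated correlation), 1 of 15 higher adjusted over the list alone. Other negative medians, with their camera adjusted p, were those of glucocorticoid response (-0.71, adjusted p = 8.4e-07), immediate early (-0.72, adjusted p = 3.72e-05), heat shock (-0.52, adjusted p = 0.000118) and mitochondrial biogenesis (-0.13, adjusted p = 0.0473, and a median of -0.0079 with no scaling) genes. They had adjusted p = 0.252 to 0.355 with an estimated correlation. Their members passed in 1 of 18 (Tsc22d3, -1.31 ± 0.28), 1 of 18, 2 of 20 and 1 of 28 cases, and in 5, 3, 7 and 3 adjusted over the list alone. Positive medians were those of fatty acid oxidation (0.26, adjusted p = 0.000311), angiogenesis (0.18, adjusted p = 0.0063) and interferon (0.61, adjusted p = 0.0018) genes. Adipocyte (1.74, adjusted p = 0.000129), endothelial (0.41, adjusted p = 0.00186) and Schwann cell (0.61, adjusted p = 0.0106) markers joined them. The positive lists had adjusted p = 0.252 to 0.381 with an estimated correlation. Adjusted over the list alone 7 of 11 adipocyte markers were positive and 1 negative, with 4 and 1 of 28 fatty acid genes, and 3 of 13 endothelial markers, 3 of 15 angiogenesis genes (1 over all genes) and 2 of 11 interferon genes were positive. The count was 746 without the batch term, where the glycolysis, mitochondrial biogenesis, heat shock, endothelial and Schwann cell lists were lost (adjusted p = 0.0612 to 0.282), as were Akap8 (0.90), Pfkm (-0.22), Tpi1 (-0.25) and Pgm1 (-0.32), with Hspa5 at -1.07. The count ranged from 9 with a depth covariate to 209 with no filter. Leaving out single libraries moved it to 2 (control 2 or HIIT 2), 6 (control 4), 11 and 12 (HIIT plus inhibitor 4 and 3), 23 (inhibitor 2), 25 (HIIT plus inhibitor 2), 63, 64, 75 and 174 (HIIT 4, 1, 5 and 3). It was 75 and 91 (inhibitor 6 and 4), 83 (control 1) and 87 (HIIT plus inhibitor 5). Without HIIT 2 the angiogenesis, fatty acid (0.10) and endothelial (0.24) calls were lost (adjusted p = 0.0708 to 0.137), with immediate early at -0.34 and interferon at 0.94. Schwann cell was lost without HIIT 3 (0.0812), where slow fibre was at 2.28, fatty acid at 0.52, endothelial at 0.65 and angiogenesis at 0.42, and mitochondrial biogenesis in 14 of 22 such fits. Endothelial and Schwann cell markers were at 0.63 and 0.93 without HIIT 1, angiogenesis at 0.28 without control 2, and mitochondrial biogenesis at -0.26 without control 3 and -0.08 without HIIT 5, HIIT 6 or inhibitor 6.

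Lactate was set directly against batch 1 HIIT. In lactate 14 genes were higher and 23 lower (1092 at an unadjusted p under 0.05), or 28 and 19 with no scaling beyond the total count. Dnmt3a (GRCm39 chromosome 12, 3851559 to 3964442), a de novo DNA methyltransferase, was higher in lactate, at 73.1 ± 11.1 against 41.7 ± 0.794 CPM (n = 6 and 3; log2 fold change 0.82 ± 0.17, adjusted p = 0.0284). Its fold change without the batch term was 0.14 and did not pass. Matrix genes Lum, lumican (109.7 ± 40.8 against 45.6 ± 3.27 CPM, 1.25 ± 0.27, adjusted p = 0.0284) and Col14a1 (1.65 ± 0.37) were higher, as was the macrophage receptor gene Csf1r (1.28 ± 0.28). Lower in lactate were Hspa5 (452 ± 43.7 against 668 ± 134 CPM, -0.56 ± 0.11, adjusted p = 0.0226), Stat3 (-0.71 ± 0.16), Noct (-1.12 ± 0.22), Mt1 (-2.61 ± 0.57) and Mt2 (-3.78 ± 0.79). All these lay on their side of the HIIT mean in 6 of 6 lactate libraries. Per1, a clock gene that glucocorticoids induce, stood at 1.82 ± 1.41 CPM in lactate, under the floor, and 16.3 ± 2.49 in HIIT (adjusted p = 0.0284). Of 18 glucocorticoid response genes 3 were lower and 15 did not pass, 9 lower adjusted over the list alone (median -1.0, camera adjusted p = 5.35e-14, and adjusted p = 0.0627 with an estimated correlation). Extracellular matrix genes were higher (median 0.73, camera adjusted p = 1.38e-11, and adjusted p = 0.158 with an estimated correlation), with 1 of 26 passed, and 9 up and 1 down adjusted over the list alone. Fibroblast markers were higher too (median 0.75, camera adjusted p = 1.1e-08, and adjusted p = 0.0627 with an estimated correlation), with 1 of 13 passed and 6 up adjusted over the list alone. Lower medians, with their camera adjusted p, were those of atrophy (-0.28, adjusted p = 9.4e-06), glycolysis (-0.24, adjusted p = 1.95e-05), heat shock (-0.27, adjusted p = 3.55e-05), immediate early (-0.54, adjusted p = 0.000213) and neutrophil (-5.28, adjusted p = 4.64e-05) genes. Those lists had adjusted p = 0.0627 to 0.268 with an estimated correlation. Of them 2 of 23 atrophy genes, 1 of 20 heat shock genes and S100a8 passed, and 8, 3 and 2 were lower adjusted over the list alone, with 5 of 18 immediate early genes. Higher medians were those of cholesterol synthesis (0.53, adjusted p = 0.00325), interferon (0.31, adjusted p = 0.00325), Schwann cell (0.64, adjusted p = 0.00462) and adipocyte (1.03, adjusted p = 0.0405) genes. These 4 had adjusted p = 0.158 to 0.498 with an estimated correlation, with 6 of 15 cholesterol, 4 of 11 interferon and 1 of 6 Schwann cell genes up and 1 of 11 adipocyte genes down adjusted over the list alone. The count was 2201 without the batch term, where the glycolysis, atrophy, heat shock, cholesterol, adipocyte and Schwann cell lists were lost (adjusted p = 0.187 to 0.995) and the folds were 0.82 for Csf1r, -0.71 for Noct and -0.92 for Hspa5, which passed. The count was 3 without the libraries under 700000 counts, 0 without lactate 3 (950 at an unadjusted p under 0.05; on the full data DESeq2 gave 71 and limma-voom 9) and 4 without lactate 2 or HIIT 2. Without HIIT 2 the immediate early call was lost (median -0.19, adjusted p = 0.363), with interferon at 0.54 and fibroblast at 0.46. Cholesterol was lost without HIIT 3 (0.14, adjusted p = 0.175), where atrophy was at -0.14 and adipocyte at 1.58, and adipocyte without HIIT 1, HIIT 2, lactate 2 or lactate 4 (0.109 to 0.379). The number of genes was 67 without lactate 6, 59 without HIIT 4 and 156 with no filter.

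**Figure D5:**
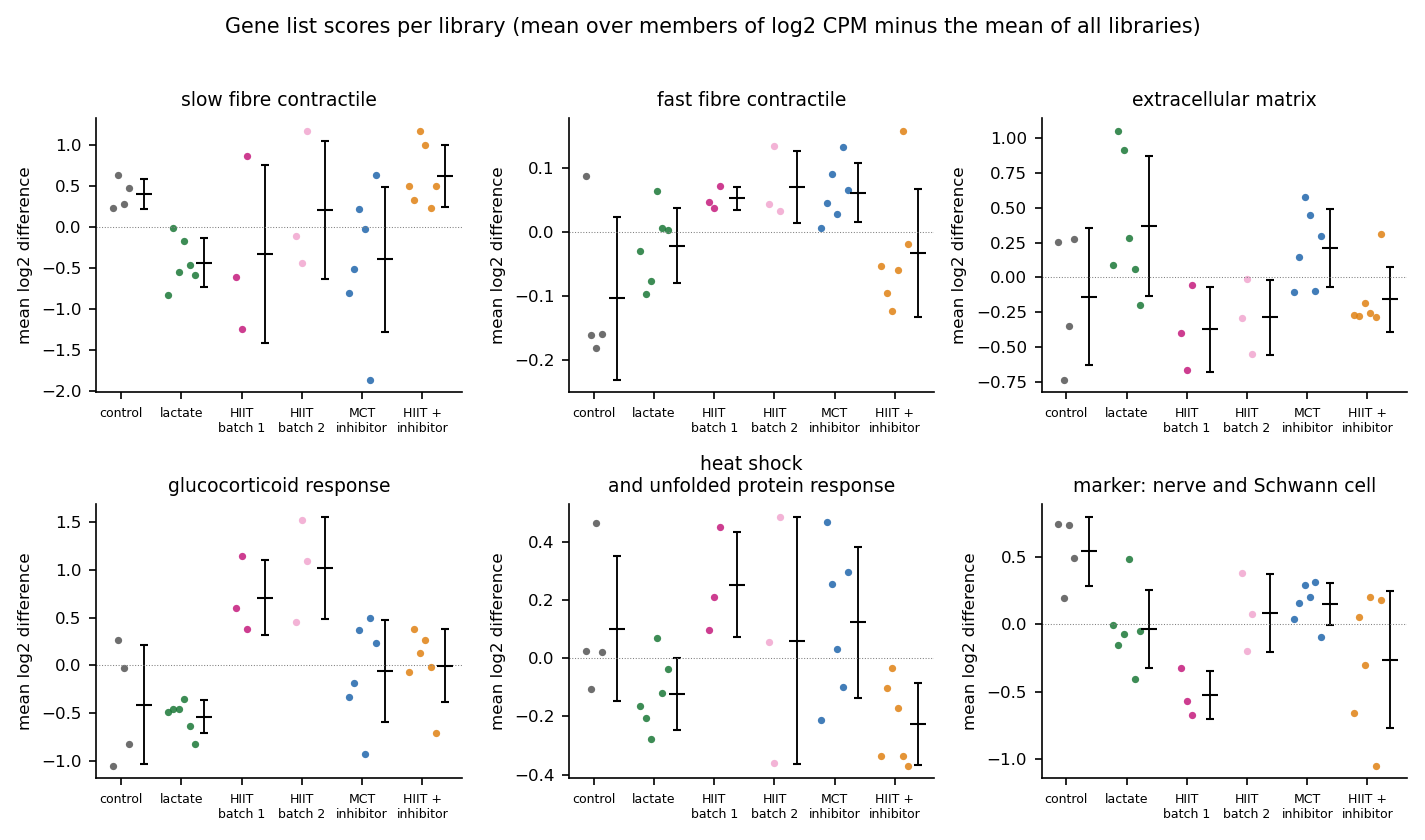
Score of 6 gene lists per library (y axis, mean over members of log2 CPM minus the mean of all libraries) by group (x axis, HIIT batches apart), 1 point per library with the mean and SD in black. Glucocorticoid response scores run from -0.824 to -0.347 in lactate and from 0.382 to 1.52 in HIIT, and slow fibre scores from -1.86 to 0.627 with the inhibitor.

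The series title links lactate and HIIT to microRNAs and DNA methylation, so the lists of that machinery are given together. In lactate vs control, 3 of 19 DNA methylation genes rose, 1 fell and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.67). Mtr, methionine synthase, fell (-1.24 ± 0.19, adjusted p = 1.46e-05). Mat2b, a regulator of S-adenosylmethionine synthesis (0.51 ± 0.11), the methyl-CpG binding gene Mbd2 (0.46 ± 0.15) and Tet3, a 5-methylcytosine dioxygenase (1.04 ± 0.32), rose. Of 18 microRNA biogenesis genes 1 rose and 3 fell, with 14 not passed and the same counts adjusted over the list alone (camera adjusted p = 0.747). Ago2, the slicing Argonaute, rose (0.51 ± 0.13, adjusted p = 0.00539), and Dgcr8, the partner of Drosha (-0.80 ± 0.23), Ago4 (-0.94 ± 0.32) and Prkra (-0.79 ± 0.25) fell. Ago2 rose in HIIT vs control (0.53 ± 0.15, adjusted p = 0.0276) and in HIIT plus inhibitor vs control (0.43 ± 0.13, adjusted p = 0.0301). In HIIT vs control 1 of 18 rose and 17 did not pass, 1 up and 2 down adjusted over the list alone. Among 16 microRNA host transcripts, 2 rose and 1 fell in lactate (3 and 3 adjusted over the list alone) and 2 rose and 1 fell in HIIT (3 and 1). Ank1, host of miR-486, rose in lactate (0.51 ± 0.10, adjusted p = 0.000418). Egfl7, host of miR-126, fell in lactate (-0.69 ± 0.19) and in HIIT (-0.94 ± 0.24), and Igf2, host of miR-483, rose in lactate (0.88 ± 0.25) and in HIIT plus inhibitor (1.14 ± 0.24, adjusted p = 0.00214). In HIIT vs control 8 of 19 DNA methylation genes had an unadjusted p under 0.05, none passed by edgeR, 1 passed by DESeq2 and 1 by limma-voom. Adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.635). Between HIIT plus inhibitor and inhibitor, 3 rose (Gadd45b among them, 1.26 ± 0.25, adjusted p = 0.00111), 2 fell (Mtr among them, -0.75 ± 0.17) and 14 did not pass, the same adjusted over the list alone. Of 19 histone acetylation and lactylation enzymes, 2 rose, 1 fell and 16 did not pass in lactate (3 and 1 adjusted over the list alone, camera adjusted p = 0.72). The acetyltransferase gene Kat2b (0.67 ± 0.17) and Aars1, an alanyl-tRNA synthetase with lactyltransferase activity (0.57 ± 0.17), rose, and the deacetylase gene Hdac7 fell (-0.53 ± 0.15). Hdac7 fell in HIIT too (-1.05 ± 0.19, adjusted p = 0.000738), and Aars1 rose there (0.76 ± 0.20). Without the batch term these were -0.57, which passed, and 0.23, which did not. Also lost then were Mat2b, Mbd2, Tet3, Ago4, Prkra, Igf2, Aars1 and Hdac7 in lactate and Ago2 in HIIT plus inhibitor vs control. The 4 microRNA gene records with enough counts to test passed in none of the 8 comparisons by edgeR, DESeq2 or limma-voom, at no unadjusted p under 0.05. Libraries primed on poly(A) do not measure mature microRNAs.

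Lactate and HIIT differed from control in the same direction at many genes. By edgeR 182 genes rose and 172 fell in both and none went opposite ways, where independent lists would share 19.4 and 18.6. Over 9110 genes, not independent replicates, Pearson's r of fold changes was 0.576. Unchanged groups with the same 4 controls gave 0.432 ± 0.0159 (SD of 20 simulations). The covariance was 0.123 against 0.0353. Genes were simulated independently, so higher values need not mean a shared effect. With the controls split 2 and 2, none shared, r averaged 0.360 (0.240 to 0.412 over 6 splits), with 63 to 141 shared calls. For HIIT and HIIT plus inhibitor, r was 0.615 (simulated 0.447 ± 0.0151, covariance 0.110 against 0.0356, split controls 0.354, 0.300 to 0.422). In both, 107 genes rose and 142 fell, against 8.12 and 11.1 for independent lists. For lactate and HIIT plus inhibitor, r was 0.671 (simulated 0.549, covariance 0.109 against 0.0358, split controls 0.382, 0.225 to 0.448), with 172 up and 277 down in both against 17.1 and 30.3. For HIIT vs control and HIIT plus inhibitor vs inhibitor, which share no library, r was 0.225 (simulated 0.000824), with 43 up and 82 down in both against 7.96 and 11. Lactate vs control and HIIT plus inhibitor vs inhibitor shared 75 up and 157 down (independent lists 16.7 and 30.2), with 5 opposite and r at 0.294. The inhibitor's own fold changes gave r of 0.474 with those of lactate (simulated 0.557, covariance 0.0620 against 0.0358, split controls 0.167, 0.0815 to 0.297). With HIIT plus inhibitor, where 1 gene was called in opposite directions, r was 0.424 (simulated 0.574, covariance 0.0466 against 0.0359, split controls 0.0919, -0.0428 to 0.251). With HIIT it was 0.487 (simulated 0.454, covariance 0.0701 against 0.0356, split controls 0.200, 0.0883 to 0.309), and 8 such pairs were computed in all.

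Batch 2 HIIT was compared with batch 1 HIIT, the only batch difference the design can estimate (3 against 3 libraries). There 1900 genes rose and 1710 fell (4320 at an unadjusted p under 0.05). Kif5b (GRCm39 chromosome 18, 6201005 to 6241524), a kinesin heavy chain, stood at 449 ± 43.3 CPM in batch 2 and 47.6 ± 6.07 in batch 1 (log2 fold change 3.24 ± 0.18, adjusted p = 4.17e-19). The nuclear RNA Malat1 averaged 2155 ± 532 CPM in batch 2 and 168 ± 66 in batch 1. Mpc1 fell (113 ± 13.2 against 332 ± 47.7 CPM, -1.56 ± 0.14, adjusted p = 5.1e-12). Kif5b, Malat1 and Mpc1 each lay on their side of the batch 1 mean in 3 of 3 libraries. Of 63 nuclear oxidative phosphorylation genes 6 rose, 34 fell and 23 did not pass, 7 up and 35 down adjusted over the list alone (median -0.47, camera adjusted p = 9.14e-05, and adjusted p = 0.987 with an estimated correlation). Glycolysis genes were lower (median -0.60, camera adjusted p = 0.00427, and adjusted p = 0.68 with an estimated correlation). Of these 2 rose, 13 fell and 8 did not pass, 2 and 16 adjusted over the list alone. Lactate transport and use was lower (median -0.35, camera adjusted p = 0.0102, and adjusted p = 0.175 with an estimated correlation), where 1 rose, 8 fell and 9 did not pass. Tricarboxylic acid cycle genes were lower as well (median -0.37, camera adjusted p = 0.0249, and adjusted p = 0.987 with an estimated correlation), where 9 fell and 8 did not pass. MicroRNA biogenesis genes were higher (median 0.49, camera adjusted p = 0.0249, and adjusted p = 0.175 with an estimated correlation). Of 18, 8 rose, 1 fell and 9 did not pass, with Dicer1 (1.69 ± 0.23) up. Over each of these last 3 lists alone the counts were the same. Of 19 DNA methylation genes 6 rose, Dnmt3a among them (1.09 ± 0.19), and 4 fell, the same over the list alone. No other group was sequenced in batch 2, so the batch cannot be told apart from any difference between these HIIT libraries.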

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

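Among the tests here, those of depth and of chance values of the controls for the genes shared by lactate and HIIT, and that of time of sampling for the glucocorticoid genes, were chosen only after the result was seen.

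The 354 genes that moved the same way in lactate and batch 1 HIIT stand out because both share the 4 controls and have shallower libraries than these. A corrected fit with total count as covariate kept 87.6% of their score difference (95% limits 67.5 to 108). The difference pools HIIT plus inhibitor with lactate and HIIT. In lactate 96.1% of the median stayed with the GC trend out (91.6 to 98.5). This argues against either as the whole cause, though no control was as shallow as lactate or batch 1 HIIT. With the covariate 109 and 76 stayed called, as medians fell from 0.721 to 0.626 (lactate) and 0.717 to 0.643 (HIIT). Chance control values were tested in libraries not used to pick the genes. Their mean signed score was 0.0901 ± 0.102 in HIIT plus inhibitor and -0.208 ± 0.0726 in inhibitor (exact permutation p = 0.00216, the smallest for 6 against 6). There the 354 had a median of 0.29 and 314 kept their sign. Control scored -0.496 ± 0.118, below inhibitor, so chance stays open as part of the cause. Time of sampling stays open, since the clock output gene Tef fell in lactate (-0.91 ± 0.16), HIIT (-1.16 ± 0.19) and HIIT plus inhibitor (-1.13 ± 0.16). A shared response to lactate and training may account for these genes, a hypothesis not tested apart from time of sampling.

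The second pattern is the difference between the HIIT batches, 3610 genes. It was not a matter of transcript length alone, since 3477 genes stayed called with a length trend taken out. More RNA from nuclei in batch 2 stays open: the measured nuclear RNAs other than Malat1 (Neat1 -0.28, Meg3 1.61, Kcnq1ot1 1.97) had a median of 1.61 with limits of -0.277 to 1.97 over genes, and a first interval from the standard errors alone (1.21 to 2.00), which left out the spread between genes, would have favoured it. The 10 splits of the 6 HIIT libraries are too few for a share under 0.05; the real one gave 3610 genes and the highest other 28. Biological differences between the HIIT libraries of the batches were not tested, because no other group was sequenced in batch 2.

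The third pattern is the lower glucocorticoid response in lactate than in HIIT, with a median of -1.0 over 18 genes. Without each batch 1 HIIT library in turn the median was -0.901, -0.952 and -1.24, and with total count as a covariate it was -1.05, so neither a single HIIT library nor depth accounts for it. Clock genes had a median absolute fold change of 0.118 (95% limits 0.0333 to 0.365, 1 of 18 called, Per1), under a bound of 1 set after the result. A median can miss a shift of few genes, so time of day stays open. The test first used 12 measured genes of the fixed list of 19 (0.110), then all 18. A stress or hormone response to training in HIIT may account for it, a hypothesis found in these data and not tested here, and the list had an adjusted p of 0.0627 with an estimated correlation.

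Other splits of the same libraries were counted for each comparison. For lactate vs control 1 of 100 splits, the real one, gave as many genes (1291, highest other 306), for HIIT vs control 1 of 35 (539, 77), for the inhibitor vs control 1 of 100 (15, 6) and for HIIT plus inhibitor vs control 1 of 100 (660, 142). For HIIT plus inhibitor vs inhibitor it was 1 of 100 (654, 172), and for lactate vs HIIT 1 of 84 (37, 13). For these the share was under 0.05. For HIIT plus inhibitor vs HIIT it was 3 of 84 (15, 23), also a share under 0.05, but 2 other splits gave as many genes or more and the count fell to 1 without HIIT 2 or HIIT plus inhibitor 4 and to 2 without HIIT plus inhibitor 6. Single libraries also lowered the 15 of inhibitor vs control (to 0 by edgeR without control 1, 946 at an unadjusted p under 0.05, and to 1 without inhibitor 5) and the 37 of lactate vs HIIT (to 0 without lactate 3, 950). The interaction gave as many in 2 of 100 (39, 88), again a share under 0.05. The split with 88 exchanges control 1 with inhibitor 6 and HIIT 3 with HIIT plus inhibitor 5, groups of opposite sign in the interaction. It called over 2 times the real count, so chance stays open there. Without each of these 4 libraries the count was 83, 75, 174 and 87. The interaction is also listed because it passed for 39 genes.

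Single libraries far from the rest of their group were found in 12 of 210 combinations of measure and group, where chance gives 10.5. Inhibitor 5 had a glycolysis score of 0.275 (nearest other 0.086), a microRNA host score of -0.447 (nearest -0.085) and Ldha at 2937 CPM (nearest 2216). Lactate 4 had scores of 0.242 for nuclear oxidative phosphorylation (nearest 0.001), 0.139 for the tricarboxylic acid cycle (-0.02), -0.771 for neutrophils (-1.37) and 1.49 for red blood cells (-0.668). Control 1 had 0.087 for fast fibres (-0.159) and -0.158 for DNA methylation (0.004). HIIT plus inhibitor 5 had 0.158 for fast fibres (-0.019) and -0.371 for adipocytes (0.207), and HIIT plus inhibitor 6 had 0.314 for extracellular matrix (-0.182).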

How the results depend on the processing

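Only the settings given above as added after the data were seen were unplanned. Of 508 calls of named genes, 27 were lost with DESeq2, 54 with limma-voom, 2 with RLE scaling, 32 without scaling, 27 without the filter, 3 at a mean of 5 CPM, 9 without the robust step, 27 with the block, 51 of 483 in the compared groups alone, 195 with the depth covariate, 81 of 490 after thinning, 35 with the GC trend out and 113 without the shallow libraries. None of those turned sign. Without the batch term 137 of 388 were lost and 5 turned sign: in HIIT vs control Dync1h1 (0.0575), Atp5pb (-0.0289), Bnip3 (-0.13) and Clec3b (0.0367), and in lactate vs HIIT Timp2 (-0.27). The lists that turned were lactate transport and use in HIIT vs control (adjusted p 0.990) and glycolysis in HIIT plus inhibitor vs HIIT (0.897). Calls in every setting and without every library numbered 28 of 97 in lactate vs control, 20 of 72 in HIIT, 34 of 68 in HIIT plus inhibitor, 37 of 73 in HIIT plus inhibitor vs inhibitor and 99 of 120 between batches, 1 each for HIIT plus inhibitor vs HIIT (Hspa5) and the interaction (Mylk4), and 0 of 14 for inhibitor vs control and 0 of 23 for lactate vs HIIT. Depth sets the floor of 3 counts at 2.39 to 5.69 CPM. Of simulated changes by 1.5 times, 16.4 to 35.8% were recovered over 4 comparisons, with depth and number of libraries not varied apart.

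Counts of called genes that moved by over 1.5 times follow, by setting; except where the batch term or fewer samples make the change, the cause was not tested. Without the batch term, lactate vs control had 640 genes (main 1291), HIIT vs control 2274 (539), inhibitor vs control 0 (15; 603 at an unadjusted p under 0.05 by edgeR), HIIT plus inhibitor vs control 252 (660), vs HIIT 2048 (15) and vs inhibitor 247 (654), lactate vs HIIT 2201 (37) and the interaction 746 (39). With a depth covariate the same comparisons had 200, 100, not moved, 272, 9, not moved, 57 and 9. Without libraries under 700000 counts, lactate vs control had 449 and lactate vs HIIT 3. After thinning, HIIT vs control had 346 and inhibitor vs control 0 (712 unadjusted, edgeR). In the compared groups alone these had 326 and 27. DESeq2 gave 52 for inhibitor vs control, 48 for HIIT plus inhibitor vs HIIT, 71 for lactate vs HIIT and 127 for the interaction. Limma-voom gave 29, 1005 for HIIT plus inhibitor vs inhibitor, 9 for lactate vs HIIT and 100 for the interaction. With no filter, inhibitor vs control had 81, HIIT plus inhibitor vs HIIT 116, lactate vs HIIT 156 and the interaction 209. Batch 1 alone gave 40, 60 and 77 for the last of these 3, no robust step 29 and 77 for HIIT plus inhibitor vs HIIT and the interaction, the GC trend out 24 and 84, mitochondrial genes out 24 for HIIT plus inhibitor vs HIIT, and RLE scaling 75 and a mean of 5 CPM 60 for the interaction. The batch difference has no value without the batch term or in batch 1 alone. Correlations with HIIT moved to 0.407 (lactate) and 0.461 (HIIT plus inhibitor) without the batch term, and to 0.360 and 0.354 with split controls. Of the 77 list calls, 0 held with an estimated correlation, 48 without the batch term and 67 with the depth covariate, and 44 held in each fit without 1 library.

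Leaving out 1 library at a time gave 803 to 1301 genes in lactate vs control, 146 to 774 in HIIT, 0 to 19 for the inhibitor (0 without control 1, 946 unadjusted, edgeR), 329 to 839 in HIIT plus inhibitor, 1 to 100 against HIIT, 438 to 772 against inhibitor, 0 to 67 for lactate vs HIIT (0 without lactate 3, 950 unadjusted), 2 to 174 for the interaction and 3088 to 3344 between batches. The correlations ran from 0.518 to 0.612 and from 0.531 to 0.639. Replicate numbers did not pair the libraries: 52 pairs with the same number had correlations of -0.226 to 0.223 (median 0.00879), and 5 of 28 libraries correlated best with their own number. With the number as a block, inhibitor vs control had 28 genes, HIIT plus inhibitor vs HIIT 24, lactate vs HIIT 72 and the interaction 66, and 74 of 77 list calls held.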

Other observations

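None of the values here was chosen before the data were seen, apart from the fixed lists and the fixed rule for named genes.

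Tef and Nr1d2 fell with training and with lactate, while most clock genes did not pass. Tef, a transcription factor driven by the clock, averaged 801 ± 84.5 CPM in control and 728 ± 60.3 with the inhibitor, against 427 ± 97.7 in lactate, 359 ± 102 in batch 1 HIIT and 365 ± 85.9 in HIIT plus inhibitor. Its fold change passed in the last 3 (adjusted p = 0.000146, 0.000443 and 1.98e-05) and not with the inhibitor (0.819). Nr1d2, a repressor of the clock, fell in the same 3 (-0.55 ± 0.11, -0.56 and -0.43, adjusted p = 0.00066, 0.00955 and 0.0114). Of the 18 measured clock and output genes, these 2 fell and 16 did not pass in lactate (2 down adjusted over the list alone, camera adjusted p = 0.567) and in HIIT (2 down, 0.44), and 1 rose, 3 fell and 14 did not pass in HIIT plus inhibitor (4 up and 5 down, 0.371). In HIIT plus inhibitor vs inhibitor, Tef (-0.99 ± 0.14), Nfil3 (-1.26 ± 0.24), Dbp (-1.08 ± 0.23) and Per2 (-1.63) fell, and Bmal1 (0.82 ± 0.18) and Nr1d1 (1.03) rose. Of the 18, 3 rose, 4 fell and 11 did not pass there, 5 and 7 over the list alone (camera adjusted p = 0.139). Dbp and Nr1d1 each lie opposite a gene with more counts.

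Nr4a3, an early response gene of exercised muscle picked after the data were seen, was uneven among the HIIT libraries. It stood at 346 CPM in HIIT 2, 218 in HIIT 5 and 285 in HIIT 6, and at 6.53, 6.88 and 10.7 in HIIT 1, 3 and 4, against 2.50 to 6.32 in control. Ppargc1a was highest in the same libraries (199, 247 and 406 CPM).

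Acyp2, Mrps28, Sdhd, Trip10 and Scn4b were higher than control in lactate, in HIIT plus inhibitor and with the inhibitor alone. Acyp2 lay between 47.4 and 116 CPM in the 4 control libraries and between 117 and 317 in the 21 libraries of the other batch 1 groups. Such a group of genes, raised against control in unlike treatments, could reflect the control libraries themselves. All 5 passed in lactate without control 1, the control with the lowest Acyp2 (Sdhd at 1.23 from 1.45), so that library alone does not account for them there. With the inhibitor alone none of the 5 passed without it (edgeR adjusted p = 0.426 to 0.774), although most of each fold stayed (0.61 from 0.80 for Acyp2, 0.77 from 0.99 for Sdhd).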
